A study of Homo sapiens with 4 samples.

How the data were processed

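The data were 4 Affymetrix expression arrays of MKN45 cells, 2 of untreated cells and 2 of cells exposed to 10 µg/ml H. pylori LPS for 8 h, grouped by their sample labels. Per the submitters' processing notes, MAS5 and RMA were used, and neither their versions nor which of them made the deposited values is given in the sources used here. The deposited values were log2 levels of 54675 probe sets, as judged from the values. Values of equal rank differed by at most 0.0978 between arrays, so the distributions were nearly the same on all 4 arrays before any step described here. Such normalization sets the overall level of the arrays equal and would hide a shift of all transcripts in 1 direction. Summaries of this kind also depend on the probes of a probe set, and those ending in _x_at or _s_at can bind transcripts of more than 1 gene. RNA was labelled with biotin by the standard Affymetrix procedure, per the labels' protocols.

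The 62 control probe sets were left out of the tests, which left 54613, and no other normalization was applied. Gene names came from the platform annotation supplied with the values. A single symbol was given for 41091 probe sets, several for 1801 and none for 11721, and no gene was named from a probe set with several. Of the probe sets with a single symbol, 41037 matched by Entrez identifier to the RefSeq gene table of assembly GRCh38.p14, which was used for names and gene biotypes only, and 54 did not match. The matching changed 0 symbols. No genome build is named with the values, so no coordinates are given. Probe sets whose mean over the 4 arrays lay under the 30 percentile (6.06) were left out, which left 38229 for the tests. Each gene was represented by the probe set with the highest mean over all arrays, which gave 16252 genes.

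LPS-treated and untreated arrays were compared in R 4.3.3 with limma 3.58.1, using lmFit and eBayes with an intensity trend, without a replicate block, and Benjamini-Hochberg adjustment across all probe sets or genes tested. All tests were two-sided, and the threshold was an adjusted p under 0.05. The moderated test had 7.06 degrees of freedom in total. Intervals are 95% intervals of the fitted difference. Unless another unit is given, differences are log2 fold changes, LPS minus untreated. Gene lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over the 21 lists tested, and again with an estimated correlation and with fry. The 22 lists covered NF-kB target chemokines and cytokines, NF-kB feedback and signalling genes, the Toll-like receptor pathway, Tribbles pseudokinases, ATF4 targets and the amino acid response, endoplasmic reticulum chaperones, interferon-stimulated genes, MAPK-driven immediate-early genes, G2/M, G1/S, cholesterol and SREBP targets, hypoxia and glycolysis, heat shock proteins, NRF2 targets, p53 targets, metallothioneins, epithelial markers, epithelial antimicrobial and barrier genes, leukocyte markers, fibroblast and endothelial markers, ribosomal proteins and histone genes. Counts adjusted over the list alone used the members of 1 list as the family of tests.

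The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold with both LPS arrays beyond both untreated arrays. Where fewer qualified, it was filled from genes at an unadjusted p under 0.01 with the same separation of arrays, given as values that did not pass. Of the 24 genes taken this way, 4 had passed, all of them higher. Symbols starting with LOC, LINC or MIR or containing -AS were not eligible. A set of 20 genes was always named: CXCL8, CXCL1, CXCL2, CXCL3, CCL20, TNFAIP3, NFKBIA, ICAM1, TRIB1, TRIB2, TRIB3, ATF4, DDIT3, ASNS, CHAC1, TLR2, TLR4, TLR5, LY96 and MYD88. In each list up to 4 members past the threshold were named, or where none passed the 2 with the smallest p.

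The procedure was tested on simulated values for the 16252 genes, with 2 arrays per group, in 5 runs. It called 7.85% of 242 genes changed 1.25-fold, 66.8% of 220 changed 1.5-fold, 97.8% of 223 changed 2-fold and 100% of 180 changed 4-fold, and 31 of 80235 unchanged genes. A list shifted by 0.25 was called in 5 of 5 runs and unshifted lists in 0 of 100 by limma's camera. In these simulations errors were independent between genes.

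Alternatives were no filter, a filter at the 50 percentile, quantile normalization, median centring, cyclic loess, eBayes without trend or with robust estimation, the replicate number as a block, an adjusted p under 0.1, an additional minimum of 1.5-fold, treat at 1.2-fold, the mean of a gene's probe sets, genes without _x_at and _s_at probe sets, and leaving out each array in turn. With 1 array left out, the lone array of its group was assumed to vary like those of the other group.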

Results

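Gene expression was measured in MKN45 cells, a human gastric epithelial line derived from an adenocarcinoma, after exposure to lipopolysaccharide (LPS), the glycolipid of the outer bacterial membrane, from the stomach bacterium Helicobacter pylori. Cells received 10 µg/ml LPS or fresh medium, and total RNA was taken 8 h later and hybridised to Affymetrix arrays. There were 2 untreated and 2 LPS-treated arrays. The series text speaks of 2 independent experiments. The p-values and intervals rest on the spread between these arrays and, through the moderated test, on the variance trend over all probe sets tested. They do not measure a spread over further experiments. Each array gave 54613 probe set values on the log2 scale, with medians of 7.004 to 7.034, and any pair of arrays correlated across probe sets at r = 0.996 to 0.998 (probe sets are not independent replicates). The median absolute difference between arrays was 0.0973 within the untreated pair, 0.0834 within the LPS pair and 0.0875 to 0.118 between the groups. The number of arrays limits the precision.

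The comparison of LPS-treated with untreated cells asked which transcripts respond to H. pylori LPS within 8 h. Chemokine genes rose most. CCL20, whose product attracts CCR6-bearing lymphocytes and dendritic cells, went from 5.65 ± 0.07 to 8.58 ± 0.12 (log2 level, mean ± SD, 2 arrays each), a 7.61-fold rise with a 95% interval of 6.56 to 8.82. CXCL1, a neutrophil attractant, rose 3.98-fold (interval 3.50 to 4.53), from 6.84 ± 0.05 to 8.83 ± 0.06. CXCL8, which encodes interleukin 8, rose 3.31-fold (interval 2.86 to 3.83), from 7.68 ± 0.14 to 9.40 ± 0.02. Its other probe set differed by 1.17 on the log2 scale and did not pass (limma adjusted p = 0.173 in the fit with no level filter). CXCL3, a relative of CXCL1, rose 2.02-fold (interval 1.76 to 2.33), from 7.45 ± 0.03 to 8.47 ± 0.11.

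These 4 genes made up the whole set past the threshold among 16252 genes tested with limma, with adjusted p-values of 9.82e-05 for CCL20, 0.000287 for CXCL1, 0.00125 for CXCL8 and 0.0246 for CXCL3. Each was higher on both LPS arrays than on both untreated arrays. No gene fell past the threshold in this limma fit, where 605 genes were higher and 1286 lower at an unadjusted p under 0.05. After quantile normalization those numbers were 916 higher and 981 lower. Treat at a minimum of 1.2-fold also called 0 lower, but it can only remove calls from the same fit, so this adds no support. CXCL3 lost its call when any 1 array was left out, with limma adjusted p-values of 0.0561 without untreated replicate 1, 0.0898 without untreated replicate 2, 0.117 without LPS replicate 1 and 0.303 without LPS replicate 2, and it also missed the threshold under treat (adjusted p = 0.0929).

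Among 38229 probe sets tested with limma, 3 passed, all higher with LPS, and they belonged to CCL20, CXCL1 and CXCL8. At an unadjusted p under 0.05, 1411 were higher and 3066 lower. By at least 1.5-fold, whatever the p, 11 were higher and 67 lower. The limma test called 0 probe sets lower, with 0.0621 as the smallest adjusted p among the lower ones. That treat also called 0 lower followed from this and adds no support. The split of calls moved with the scaling of the arrays, to 4 higher and 4 lower after quantile normalization or cyclic loess and to 6 higher and 11 lower after median centring. Without untreated replicate 1 the count was 11 (5 higher, 6 lower), and 4 of those 6 lower probe sets belonged to MALAT1.

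**Figure D1:**
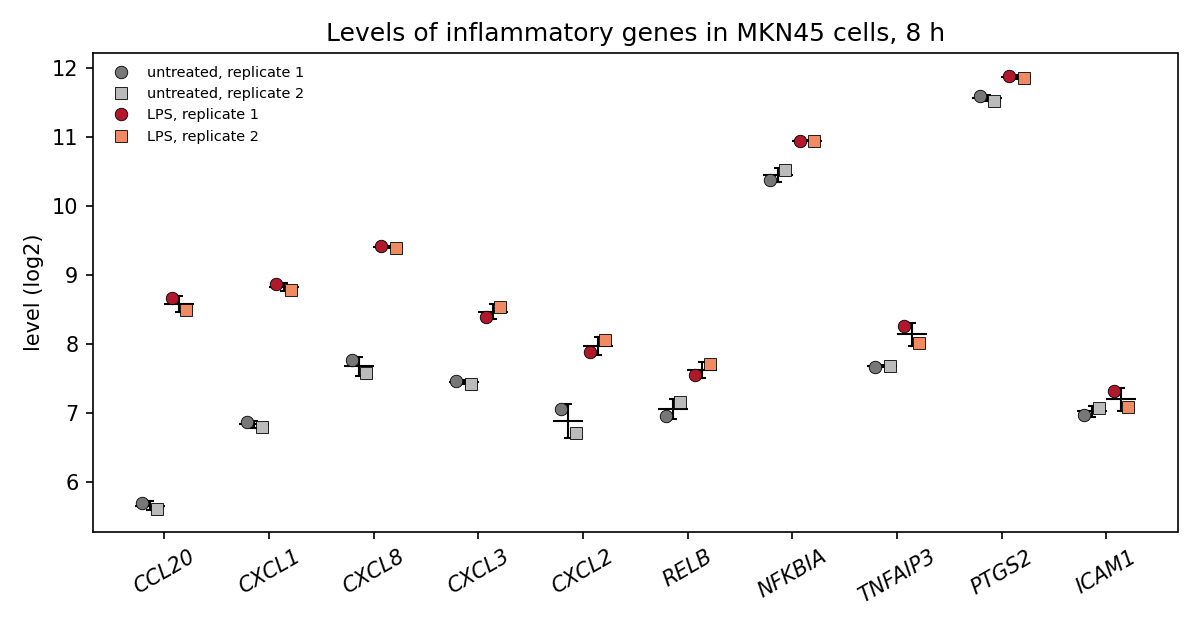
Level of 10 inflammatory genes on each of the 4 arrays (vertical axis, log2), with circles for replicate 1, squares for replicate 2, horizontal bars for the group mean and whiskers for the SD (n = 2). CCL20 lies at 5.70 and 5.61 on the untreated arrays and at 8.67 and 8.50 on the LPS arrays, while ICAM1 differs by 0.18 between the group means.

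Other targets and regulators of nuclear factor kappa B (NF-kB), a transcription factor of inflammation, did not pass. CXCL2, a further neutrophil attractant, was 2.13-fold higher (6.88 ± 0.25 to 7.97 ± 0.13, limma adjusted p = 0.178) on 1 probe set, while its other 2 probe sets, both under the level filter, differed by 0.05 and -0.15. The log2 fold change of CXCL2 was 0.92 to 1.27 with 1 array left out. RELB, an NF-kB subunit, was 1.48-fold higher (limma adjusted p = 0.257), and NFKBIA, which encodes the inhibitor that holds NF-kB in the cytoplasm, was 1.41-fold higher (adjusted p = 0.253). The second probe set of NFKBIA differed by -0.0058. TNFAIP3, a deubiquitinase that ends NF-kB signalling, was 1.38-fold higher (limma adjusted p = 0.285). The adhesion molecule ICAM1 differed by 0.18 (interval -0.06 to 0.41) on its brightest probe set, and by 0.84 and 0.08 on its other 2.

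Further genes with the largest higher values, none past the limma threshold, were the transmembrane protein TMEFF2 (log2 fold change 0.54, against -0.15 and 0.04 on 2 probe sets under the filter), the heparan sulfate proteoglycan SDC4 (0.51), the fatty acid synthase FASN (0.50, against -0.15 on its other probe set), IL2 (0.50) and the zinc transporter SLC39A1 (0.49), with adjusted p-values of 0.257 to 0.328. The IL2 probe set lay at 6.10 in untreated cells, against a filter of 6.06, and its other probe set differed by -0.06. MALAT1, an abundant nuclear long non-coding RNA, had the lowest log2 fold change of the named genes, at -1.06 (12.65 ± 0.37 to 11.59 ± 0.13, limma adjusted p = 0.257), and all 12 of its probe sets were lower, 10 of them with both LPS arrays below both untreated arrays. Its difference was -1.32 to -0.80 with 1 array left out, and -0.31 on its only probe set outside the cross-hybridising _x_at and _s_at types. EIF5A, a translation factor, differed by -0.65 (limma adjusted p = 0.303) and was lower on 3 of 3 probe sets, FNTB, a farnesyltransferase subunit, by -0.64 (0.199), and ID2, an inhibitor of basic helix-loop-helix factors, by -0.55 (0.253). The remaining named genes in this direction were ZNF224 (-0.67, with 5 further probe sets from -0.42 to -0.03), C7orf57 (-0.67), KDM5A (-0.58, with 4 further probe sets from -0.42 to 0.0027), PTGR3 (-0.57), SNORA21 (-0.56), PBLD, SLC12A2-DT and ZBED6 (each -0.55). Other probe sets above the filter went against this direction for SLC12A2-DT, at 0.10 and 0.03, and for ZBED6, at 0.10, and the other PBLD probe set, under the filter, differed by -0.13.

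**Figure D2:**
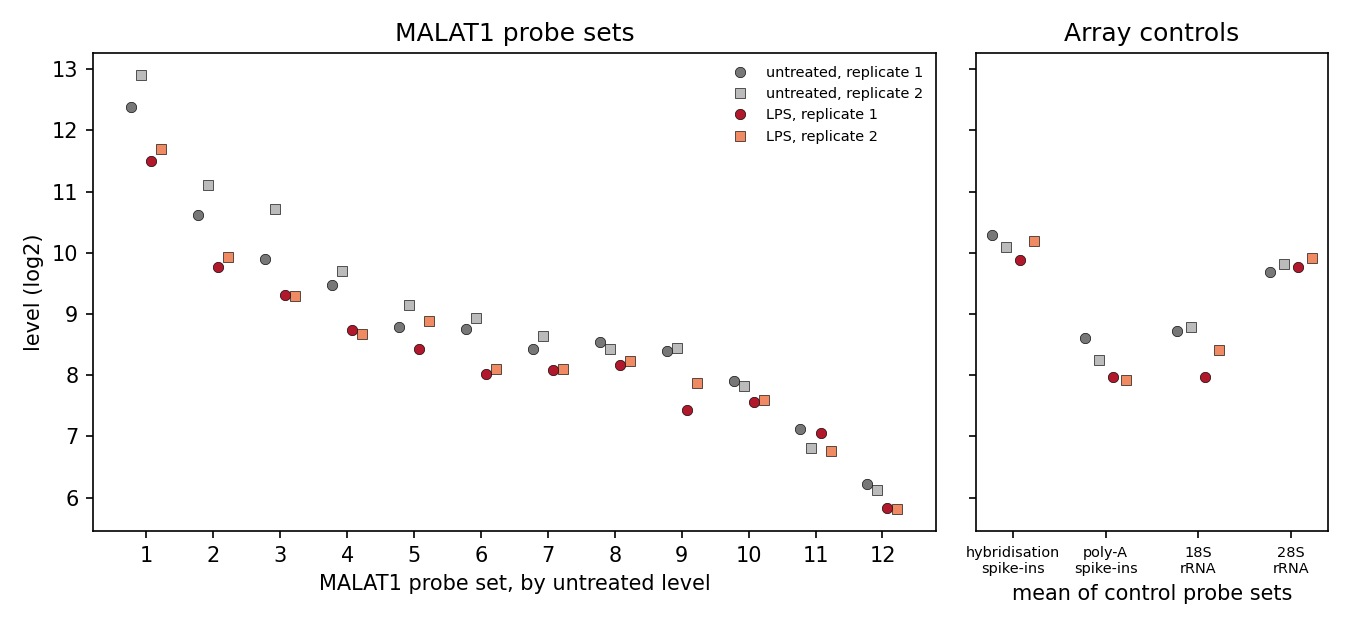
Level on each array (vertical axis, log2) of the 12 MALAT1 probe sets, ordered by untreated level, and of 4 classes of array controls as means over their probe sets. The brightest MALAT1 probe set lies at 12.39 and 12.91 on the untreated arrays and at 11.50 and 11.69 on the LPS arrays, and the poly-A spike-ins lie at 8.60 and 8.25 against 7.98 and 7.92.

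The gene list tests asked whether functional groups shifted together. Of the NF-kB target chemokines and cytokines, 4 of 19 measured members rose over all genes tested and 6 adjusted over the list alone. The 2 added members were CXCL2 and LTB (log2 fold change 0.43), the latter named after its value was seen. The list shifted upward by limma's camera (median log2 fold change 0.13, adjusted p = 1.36e-09; adjusted p = 0.298 with an estimated correlation). Of the NF-kB feedback and signalling genes, 0 of 22 passed over all genes in limma and 6 rose adjusted over the list alone, with 7 higher and 0 lower at an unadjusted p under 0.05. RELB, NFKBIA and TNFAIP3 were among the 6. That list also shifted upward by camera (median 0.11, adjusted p = 0.000101; adjusted p = 0.298 with an estimated correlation). Limma's fry, which tests whether a list moves on balance 1 way, gave adjusted p-values of 0.0366 and 0.038 for these lists.

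Genes of hypoxia and glycolysis shifted upward as a list in camera, with smaller differences (30 measured, median 0.07, limma adjusted p = 0.000254; adjusted p = 0.298 with an estimated correlation). No member passed in limma over all genes or adjusted over the list alone (7 higher and 0 lower at an unadjusted p under 0.05), and fry gave 0.138. The glucose transporter SLC2A1 was 1.24-fold higher and the glycolytic enzyme PGAM1 1.12-fold higher. The G2/M cell cycle list shifted downward (34 measured, median -0.07, camera adjusted p = 0.00245 in limma; adjusted p = 0.599 with an estimated correlation), and fry gave 0.305. In that list 0 members fell over all genes in limma, 7 fell adjusted over the list alone, and 12 were lower and 1 higher at an unadjusted p under 0.05. NUSAP1, a spindle protein, differed by -0.24 and HMMR by -0.22. The G2/M median was -0.02 after quantile normalization or cyclic loess. Bright genes were lower in general. Over all genes in 10 bins of level, medians were -0.05, -0.05 and -0.03 in bins 8, 9 and 10 (mean levels 10 to 12.3). In bin 1, the faintest, the median was 0.03. G2/M members lay at 8.76 to 13.03 in untreated cells, most of them at such high levels. Camera compared them with genes of all levels, so this trend was not removed from the call. None of the 4 list calls held with an estimated correlation, and both NF-kB lists held in fry. The estimated correlation was 0.0215 in the chemokine list, -0.0349 in the NF-kB feedback list, -0.00715 in the hypoxia list and 0.247 in the G2/M list. With an estimated correlation, camera also takes its p-values from the few residual degrees of freedom of 4 arrays. The loss of the upward calls therefore does not show that correlation between genes undid them.

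**Figure D3:**
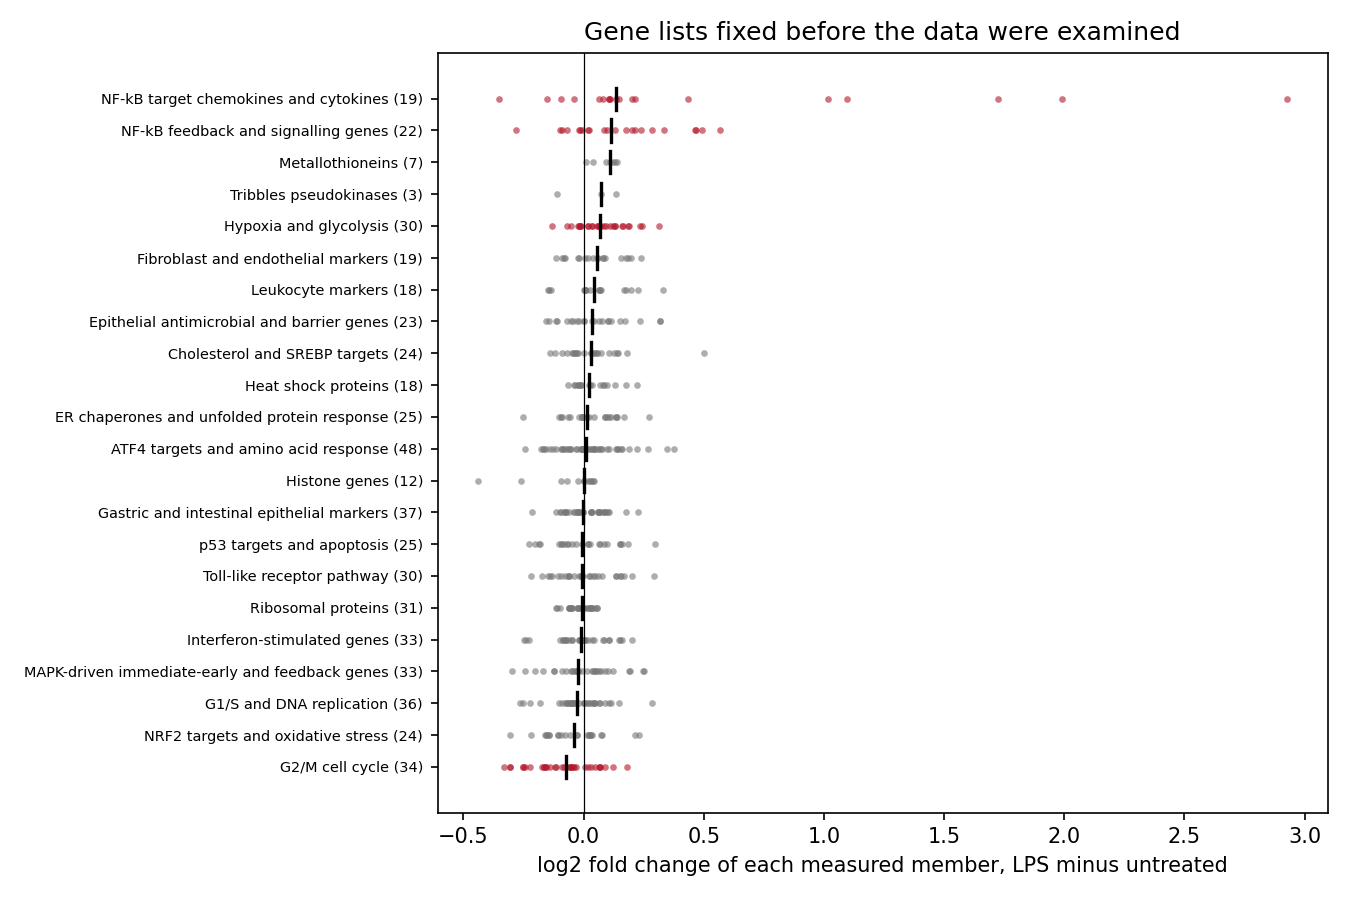
Log2 fold change (horizontal axis, LPS minus untreated) of each measured member of the 22 gene lists, with the number measured in brackets, a black bar at the median and red for the 4 lists that passed in camera. The chemokine and cytokine list has members up to 2.93, while the median of the other lists lies between -0.07 and 0.11.

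The receptors and adaptors that sense bacterial products were compared because the ligand was LPS. TLR4, the LPS receptor, lay at 7.75 ± 0.17 and 7.82 ± 0.0034 (log2 fold change 0.06, interval -0.17 to 0.29), and its other 3 probe sets differed by -0.0025 to 0.27. LY96, which encodes its co-receptor MD-2, lay under the level filter at 3.93 in untreated and 3.92 in LPS-treated cells, the 1.81 and 1.71 percentiles of all probe sets. TLR2 differed by 0.15 (interval -0.04 to 0.35), TLR5 by -0.02 (interval -0.25 to 0.21) and the adaptor MYD88 by 0.08 (interval -0.07 to 0.22). No member of the Toll-like receptor pathway list passed in limma over all genes or adjusted over the list alone (30 measured, 1 higher and 0 lower at an unadjusted p under 0.05). TLR8 (0.29) and TAB2 (-0.22, against 0.13 on another probe set above the filter) had its smallest p-values, and the list was not called (camera adjusted p = 0.691 in limma, fry 0.92).

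The Tribbles pseudokinases, scaffolds that regulate kinase signalling, had 3 measured members and were too few for a list test, with 0 passing in limma and 0 at an unadjusted p under 0.05. TRIB3 differed by 0.13 (interval -0.07 to 0.34), TRIB1 by 0.07 (interval -0.07 to 0.21) and TRIB2 by -0.11 (interval -0.32 to 0.10). The stress regulator ATF4 differed by 0.04 (interval -0.09 to 0.17), and its targets DDIT3 by 0.03, ASNS by -0.13 and CHAC1 by 0.14. The list of ATF4 targets and amino acid response genes (48 measured) had 0 members past the limma threshold over all genes or adjusted over the list alone, with 6 higher and 3 lower at an unadjusted p under 0.05 (camera adjusted p = 0.296, fry 0.709). Its smallest p-values belonged to the amino acid transporter SLC7A5 (0.38) and DDIT4 (0.27). Endoplasmic reticulum chaperones and unfolded protein response genes (25 measured) were not called (limma camera adjusted p = 0.134, fry 0.39), with MANF at 0.13 and ATF6 at -0.25 (other probe sets from -0.29 to 0.16).

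**Figure D4:**
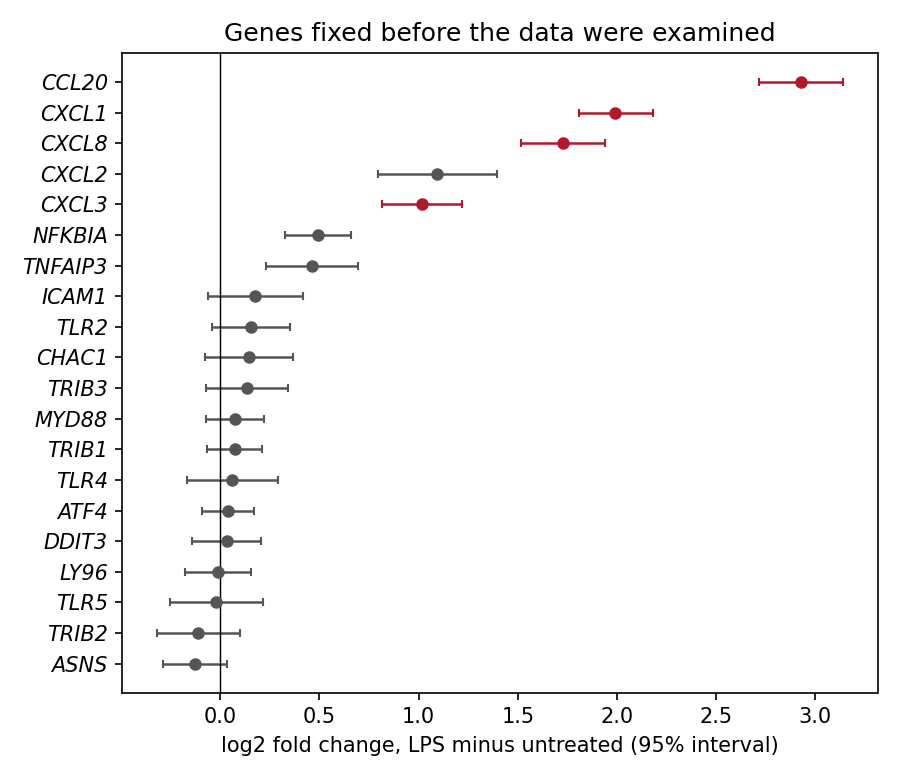
Log2 fold change (horizontal axis, LPS minus untreated) with its 95% interval for the 20 genes named in advance, in red where the limma adjusted p passed. CCL20, CXCL1, CXCL8 and CXCL3 passed, and the interval of TRIB3 reached from -0.07 to 0.34; LY96, under the level filter, is drawn from the fit without it.

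Further lists gave single members past the threshold only when adjusted over the list alone, with 0 over all genes in limma. These were PTGS2, the inducible prostaglandin synthase, among 23 epithelial antimicrobial and barrier genes (0.32, 1.24-fold higher; the elastase inhibitor PI3 also differed by 0.32), FASN among 24 cholesterol and SREBP targets (HSD17B7 differed by -0.14), the chaperone HSP90AB1 among 18 heat shock proteins (0.18; DNAJB1 0.22), PHLDA1 among 33 MAPK-driven immediate-early and feedback genes (0.25, with other probe sets from -0.03 to 0.37; DUSP6 -0.24) and H2BC4 among 12 histone genes, lower by a log2 fold change of -0.44 (H2AC6 -0.26). By camera in limma these lists had adjusted p-values of 0.203, 0.248, 0.134, 0.691 and 0.47, in that order. Their counts at an unadjusted p under 0.05 were 3 higher and 1 lower, 1 and 1, 2 and 0, 4 and 3, and 0 and 2, and fry adjusted p-values were 0.246, 0.709, 0.413, 0.94 and 0.468.

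In the remaining lists 0 members passed in limma over all genes or adjusted over the list alone, and no list was called by camera or fry. Interferon-stimulated genes (33 measured) had a median of -0.0092 and a camera adjusted p of 0.936, with IFITM1 at -0.23 and GBP2 at -0.24, and 1 higher and 2 lower at an unadjusted p under 0.05. NRF2 targets and oxidative stress genes (24 measured) had a median of -0.04 and a camera adjusted p of 0.134, with ABCC3 at -0.31 and AKR1C3 at -0.16, and 1 higher and 6 lower. G1/S and DNA replication genes (36 measured) had a median of -0.03 and a camera adjusted p of 0.691, with RFC4 at -0.25 and PRIM1 at -0.27, and 0 higher and 3 lower. The p53 targets and apoptosis genes (25 measured) had a median of -0.0070 and a camera adjusted p of 0.77, with the cyclin-dependent kinase inhibitor CDKN1A at 0.30 and TNFRSF10A at -0.20 (other probe sets -0.07 and 0.08), and 1 higher and 1 lower. Metallothioneins (7 measured) had a median of 0.11 and a camera adjusted p of 0.0756, with MT1F at 0.14 and MT1X at 0.13, and 0 higher and 0 lower. Ribosomal proteins (31 measured) had a median of -0.0079 and a camera adjusted p of 0.334, with RPL11 at -0.11 and RPL3 at -0.12, and 1 higher and 5 lower. Fry adjusted p-values of these lists were 0.92, 0.246, 0.537, 0.92, 0.312 and 0.246, in that order.

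Marker lists of cell types were not called either. Gastric and intestinal epithelial markers (37 measured) had a median of -0.0047 and a limma camera adjusted p of 0.691, with GATA6 at -0.22 and CDX2 at 0.23. Leukocyte markers (18 measured, median 0.04, camera adjusted p = 0.207 in limma) included CD53 at 0.33 and lysozyme, LYZ, at -0.15. Fibroblast and endothelial markers (19 measured, median 0.06, camera adjusted p = 0.134 in limma) included VIM at 0.24 and PDGFRB at 0.18. Fry adjusted p-values of these lists were 0.92, 0.692 and 0.537, and 1, 2 and 1 of their members were higher and 1, 1 and 0 lower at an unadjusted p under 0.05. The test and the median differed in sign for the Toll-like receptor, interferon, MAPK, p53 and gastric lists, which had a camera direction upward and a median under 0, and for the histone list, which had a camera direction downward and a median of 0.0013. Quantile normalization or cyclic loess turned the sign of the median in the Toll-like receptor, interferon, MAPK, G1/S, p53, gastric and ribosomal protein lists, none of which was called. The mean was above 0 in the Toll-like receptor list (0.0047) and the gastric list (0.0075), and it was -0.06 in the histone list.

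Array controls differed between the groups. Poly-A spike-ins, bacterial transcripts added to the RNA before labelling, averaged 8.60 and 8.25 on the untreated arrays and 7.98 and 7.92 on the LPS arrays, a difference of -0.48, and all 24 of their probe sets were lower on both LPS arrays than on both untreated arrays. Hybridisation spike-ins, added after labelling, differed by -0.15 (within-group SD 0.18). Probe sets of 18S ribosomal RNA differed by -0.57 (within-group SD 0.22) and those of 28S by 0.10 (within-group SD 0.10). The difference between the 3' and 5' probe sets of ACTB, a measure of RNA integrity, was 0.64 and 0.86 in untreated and 0.39 and 0.63 in LPS-treated cells, and that of GAPDH differed by 0.0093 between the group means. These differences ran along with every group of genes that was higher or lower with LPS, the chemokine list and the G2/M list included.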

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

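The control probe sets were examined only after the other results were seen. Of the 62 control probe sets, which enter no comparison between groups of genes, 24 were lower and 3 higher on the LPS arrays at a limma adjusted p under 0.05 over the controls. The 24 lower ones were 21 poly-A spike-ins and the 3 probe sets of 18S ribosomal RNA, with log2 differences of -0.82 to -0.35. The 3 higher ones were the 5' probe set of ACTB (log2 difference 0.33, adjusted p = 0.0105 by limma), its middle probe set (0.19, adjusted p = 0.00798 by limma) and the 3' probe set of 28S ribosomal RNA (0.30, adjusted p = 0.0381 by limma). The ACTB probe set used for the gene level differed by 0.06. No explanation for these differences was tested.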

How the results depend on the processing

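All alternatives given here were chosen beforehand. The 4 genes called (CCL20, CXCL1, CXCL8 and CXCL3) were all called in 11 of 17 alternatives, and the count of genes was 3 to 5 with 1 array left out. CCL20 and CXCL1 passed in all 17, with log2 fold changes of 2.84 to 3.01 and 1.95 to 2.03. CXCL8 passed wherever it was measured, which excludes the fit without _x_at and _s_at probe sets. CXCL3 missed the threshold under treat and without any 1 array, with limma adjusted p-values of 0.00225 to 0.303 over its alternatives. The labels share only replicate numbers between the groups, and the replicate 2 minus replicate 1 differences of the groups correlated at r = 0.214 across probe sets. With the replicate block 7 genes were called, the 4 above with SDC4 higher and EIF5A and MALAT1 lower, and 3 probe sets. With 1 array left out, CXCL2 (higher) and MALAT1 (lower) each gained a call in 1 fit. Over the fits with 1 array left out, their log2 fold changes were 0.92 to 1.27 and -1.32 to -0.80. Calls were also gained for CXCL2 under median centring, and for CXCL2 and FNTB in the fit on means of probe sets above the filter. Each of these genes had 1 such probe set, so its own value stayed the same there (1.09 and -0.64), and the cause was not tested.

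The count of probe sets called, 3 in the analysis as reported, was 5 with the filter at the 50 percentile or robust eBayes, 8 with quantile normalization or cyclic loess, 17 with median centring, 9 at an adjusted p under 0.1, and 2 to 11 with 1 array left out. The count of gene lists called, 4 as reported, was 8 with quantile normalization, 2 with fry, 0 with an estimated correlation in limma's camera, and 4 to 6 with 1 array left out. The lists added by quantile normalization were endoplasmic reticulum chaperones, cholesterol targets, heat shock proteins and metallothioneins. The causes of these differences were not tested. The sign turned for NFKBIA (-0.0058) and TLR4 (-0.0025) without _x_at and _s_at probe sets, where another probe set was used. It also turned with arrays left out for ATF4 (-0.013 to 0.093), TLR4 (-0.059 to 0.18) and TLR5 (-0.12 to 0.085), none of which had passed. Among the list medians 45 values moved by more than the spread within groups, in 12 lists, 219 did not, and no called list turned its sign. Scaling moved the median of all genes by under 0.1, from -0.0047 to 0.01 with quantile normalization or cyclic loess and -0.02 with median centring. Signal over background limited LY96 and 2 CXCL2 probe sets, which lay under the filter. The pseudocount was not run, because the values were already on a log scale.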

Other observations

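The gene families, the 28S and MALAT1 probe set tests, the test of the brightest lncRNA genes and the CXCL2 test were chosen only after the results were seen. Among 15 families picked by symbol, the genes named HLA had 17 of 19 members above 0 (median log2 fold change 0.07), keratins 23 of 31 (0.06) and tubulins 11 of 15 (0.06). Centrosomal and centromere proteins (CEP and CENP) had 42 of 53 members below 0 (median -0.08), with 3 of the 53 also in the G2/M list, and zinc finger genes named ZNF had 254 of 374 below 0 (-0.05). By limma's camera the adjusted p-values were 0.00332, 0.00362, 0.00362, 0.00282 and 0.0139, in that order. None held with an estimated correlation (adjusted p = 0.497 to 0.586) or in fry (0.237 to 0.363). The sign of these 5 medians was the same after quantile normalization, median centring and cyclic loess, although that of the CEP and CENP genes was -0.04 and that of the ZNF genes -0.02 after quantile normalization.

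The other 10 families were not called. These included proteasome subunits (34 genes, median -0.02), mitochondrial complex I (41, -0.03), mitochondrial ribosomal proteins (75, -0.03) and translation initiation factors (47, -0.02), and the sign of these 4 medians turned after quantile normalization or cyclic loess. Chemokines outside the NF-kB list had a median of 0.04 over 14 genes (limma camera adjusted p = 0.243), and no member passed. When the arrays were split by replicate number in place of treatment, limma called 0 genes, with 326 at an unadjusted p under 0.05, and the crossed split called 0, with 174, against 4 and 1891 for LPS against untreated. In both other splits each group mixed LPS and untreated arrays. Differences that follow treatment then count as spread within groups, so the genes called for LPS could hardly be called there. The lower counts of these splits therefore add no support. With 2 arrays per group there are 3 splits, too few for a share under 0.05.

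The lower MALAT1 values with LPS were weighed against technical explanations. A single faulty probe set is argued against by 10 of 12 probe sets with both LPS arrays below both untreated arrays. The only probe set outside the _x_at and _s_at types overlapped between the groups (8.787 and 9.154 untreated, 8.432 and 8.884 with LPS). Binding of other transcripts to the remaining probe sets was not tested. Less ribosomal RNA carried into labelling would lower both ribosomal classes, and 28S differed by 0.0966 while 18S differed by -0.57. These values describe the ribosomal controls, and a link from them to MALAT1 was not tested. The lower poly-A spike-ins (-0.48) were not weighed against the MALAT1 values either. Less nuclear or unprocessed RNA in the LPS samples and an effect of LPS on MALAT1, which was not tested, cannot be told apart: the median of 1470 lncRNA genes lay at the 92.1 percentile of level-matched lists of protein-coding genes, but at 98 and 100 in the other splits of the arrays, so it did not decide. The 21 lncRNA genes above the 75 percentile of levels lay at 2.1, against 48.2 and 89.5 in the other splits, and the 20 without MALAT1 lay at 3.57 (6 lower and 1 higher at an unadjusted p under 0.05), but these differed by -0.45 to 0.23, which argues only against a loss of all of them as large as that of MALAT1 (-1.06).

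The higher CXCL2 value rested on 1 probe set of the _x_at type, which could bind transcripts of its relatives CXCL1 and CXCL3, which rose. The other 2 CXCL2 probe sets differed by at most 0.0531 upward, but both lay under the level filter. A rise of CXCL2 itself and cross-hybridisation therefore cannot be told apart here.

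At an unadjusted p under 0.05 more genes were lower than higher, 2.13 times as many. The other splits of the arrays were also unbalanced, with ratios of 0.583 (replicate 2 against 1, 120 lower and 206 higher) and 0.526 (crossed, 60 lower and 114 higher). Their direction depends only on which pair of arrays is subtracted from the other. Imbalance thus also arose where the split did not follow treatment. Differences between LPS and untreated arrays also followed the level of the genes. In 10 bins of level, the median was 0.03 in bin 1, the faintest, and -0.05, -0.05 and -0.03 in bins 8, 9 and 10. A level-dependent distortion left in the deposited values and a true shift cannot be told apart: the ratio was 1.19 after cyclic loess and 1.07 after quantile normalization, but the former centres the differences at each level and the latter equalizes the distributions, whatever their origin. Untreated replicate 1 alone is argued against by a ratio of 2.07 without it. Non-coding transcripts alone are argued against by a ratio of 0.938 among lncRNA genes (60 lower and 64 higher). The ratio was 2.29 among protein-coding genes, but these were 14384 of the 16252 genes, so it had to lie near that of all genes. The ratio was 1.51 without LPS replicate 1 and 1.77 without LPS replicate 2.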
